A study of Homo sapiens with 41 samples.

How the data were processed

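RNA from 2 human cell lines, LX-2 and HMLE, was sequenced in 32 samples, 16 per line, with 2 samples in each of 16 groups of line, hairpin and condition. Per the labels, RNA was extracted with Qiagen RNeasy and libraries were made with a SMARTer mRNA-Seq kit. Per the submitters' processing notes, cutadapt, Bowtie2, STAR, HOMER, featureCounts and DESeq were used with builds hg19 and hg38; the notes give no versions and do not say which tool or build served which data type. The deposited values are counts per gene, 1 file per sample, whole numbers for 58735 Ensembl genes, of which 58207 carried a symbol. Blank lines in the files held no gene. The 9 ChIP-seq samples of LX-2 (input, ATF4 and H3K27ac) were not analysed here.

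Total counts had a median of 17961921 in LX-2 and of 21444074 in HMLE. The files of the 2 HMLE shATF4 AA_Dep samples were byte for byte the same and both named replicate 1 in their header, so that group has 1 library, which was assumed to vary like the other groups. SDs next to group means are therefore absent for it.

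Counts were analysed with edgeR 4.0.16 in R 4.3.3 (with limma 3.58.1 and the data reader data.table at version 1.17.8). Each line was fitted with all its groups, and both lines were fitted together for comparisons between them. Genes were kept by filterByExpr with the groups (17772 in LX-2, 17940 in HMLE and 20689 in both), scaled by TMM, and tested with the quasi-likelihood F test. P-values were adjusted by Benjamini and Hochberg, with 0.05 as threshold. Log2 changes are from the fit, and their SE is the absolute log2 change over the square root of F. Levels are CPM, TMM-normalised where called normalised and with the SD over libraries. Differences of responses between hairpins, and between lines, were tested as interactions. Comparisons, gene lists and the rule for named genes were chosen before the data were examined.

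Gene lists, 27 in all, were written before the data were examined, and those with at least 5 tested genes were compared with all other genes by camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01. P-values of camera are adjusted over the lists. A list's counts are of genes past the threshold over all genes, and "over the list alone" means adjusted within the list. The median is over its tested genes. Members absent from 1 group are also given at their bound where that changes the median. That second median leaves out members with at most 3 counts over the group where they are higher.

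Named genes were drawn from ATF4 in every comparison and TWIST1 in HMLE; from each list up to 4 members past the threshold with the largest change and up to 2 others; and the 5 largest rises and 5 largest falls past the threshold with a symbol, at least 5 CPM in the higher group and both libraries of one group above both of the other. Clone names, LOC names and pseudogenes were left out of the last part. Genes with near-identical copies were left unnamed or given as uncertain, a choice made after the values were seen. Some genes picked by this rule are not reported here. Genes named outside this rule, such as ACTA2 and TWIST2, were chosen after their values were seen. A fold against a group with no counts is a lower bound with 3 counts over the group as floor, and such bounds and intervals cover counting error alone. For windows of neighbouring genes, genes were ordered by the GRCh38.p14 annotation and 100 neighbours made 1 window, and positions served only for this order.

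Overlaps of 2 responses are set against independent lists, and, where the compared groups share libraries, against 20 simulated data sets with no change. Simulated data were also used to check the fit: of 67 genes given a log2 change of 1 the test recovered 97% in HMLE, 92.5% in LX-2 with 15 libraries and 1.49% with 16. Unchanged genes made up 8% of the calls in HMLE, 7.14% with 15 LX-2 libraries and 0% with 16. Alternatives tried were DESeq2's size factors in edgeR, the DESeq2 1.42.0 Wald test, no count filter, the replicate number as block, only the compared groups in the fit, a minimum absolute log2 change of 1, and leaving out each library in turn. Estimated correlation and the fry test were tried for the lists. Added after the data were seen were the LX-2 and between-line results without LX-2 shCtrl thapsigargin replicate 2 in comparisons that do not use it, and the removal of window medians.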

Results

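The series examined ATF4, a transcription factor of the integrated stress response, in 2 human cell lines by RNA sequencing. LX-2 is an immortalised line of hepatic stellate cells, the collagen-producing cells of liver fibrosis, and HMLE is an immortalised line of mammary epithelial cells. Cells carried a control hairpin (shCtrl) or a hairpin against ATF4 (shATF4). LX-2 cells received DMSO as vehicle, TGFbeta (the main fibrogenic cytokine), thapsigargin (which empties the calcium store of the ER and so causes ER stress), or the condition labelled AA_Dep, read here as amino acid deprivation. HMLE cells had DMSO, thapsigargin and AA_Dep as well, and Twist_OE, overexpression of the EMT transcription factor Twist, in place of TGFbeta. The labels give no dose or duration. These conditions made 16 groups of 2 samples each, 32 in all. Total counts ran from 14551191 to 18776430 per sample in LX-2 and from 15956909 to 23243132 in HMLE.

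Both HMLE shATF4 AA_Dep samples held identical values for every gene, so they entered as 1 library and 31 libraries were used. In LX-2, shCtrl thapsigargin replicate 2 differed from its replicate: the correlation of log2 CPM between them was 0.803, against at least 0.986 in the other LX-2 pairs, and it had counts for 15840 genes against 22912 to 24255 in the other LX-2 libraries. With it, the coefficient of biological variation across LX-2 was 29.5%, and without it 9.21%, against 5.24% in HMLE. Totals of genes called by edgeR in LX-2 are therefore given both with all 16 LX-2 libraries and with the 15 that remain without this discordant library, and counts within gene lists are with 16 unless stated.

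ATF4 RNA was lower in every shATF4 library than in every shCtrl library of the same line and condition. In LX-2 shCtrl cells it stood at 226 and 245 CPM in DMSO, 273 and 281 in TGFbeta, 670 and 785 in thapsigargin, and 785 and 618 in AA_Dep. With shATF4 the LX-2 values were 134 and 120 in DMSO, 132 and 133 in TGFbeta, 233 and 210 in thapsigargin, and 240 and 235 in AA_Dep. In HMLE shCtrl cells ATF4 stood at 433 and 455 CPM in DMSO, 285 and 310 in Twist_OE, 688 and 643 in thapsigargin, and 947 and 955 in AA_Dep. HMLE shATF4 cells had 125 and 120 CPM in DMSO, 150 and 159 in Twist_OE, 101 and 103 in thapsigargin, and 134 in the single AA_Dep library. ATF4 fell by 1.85 on the log2 scale with shATF4 in HMLE DMSO (adjusted p = 1.5e-14), by a log2 change of -0.97 in Twist_OE (5e-12), -2.72 in thapsigargin (3.3e-17) and -2.78 in AA_Dep (1.8e-15). The corresponding log2 changes in LX-2 were -0.92 in DMSO, -1.08 in TGFbeta, -2.26 in thapsigargin and -1.65 in AA_Dep. Of these LX-2 changes, that in thapsigargin passed with all 16 libraries (adjusted p = 0.017, and a log2 change of -1.58 without the discordant library), and the others had adjusted p of 0.43, 0.13 and 0.11. Without the discordant library they had 3e-05, 2.1e-06 and 1.5e-07. Among shCtrl cells, ATF4 rose by 2.08 ± 0.30 (log2, SE) in LX-2 thapsigargin (1.41 without the discordant library) and by 1.54 in LX-2 AA_Dep (adjusted p = 0.00083 and 0.0059), and by 0.63 and 0.99 in HMLE (4e-09 and 2.9e-12). In LX-2 TGFbeta the ATF4 change was 0.36 (adjusted p = 0.83, and 0.016 without the discordant library).

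**Figure D1:**
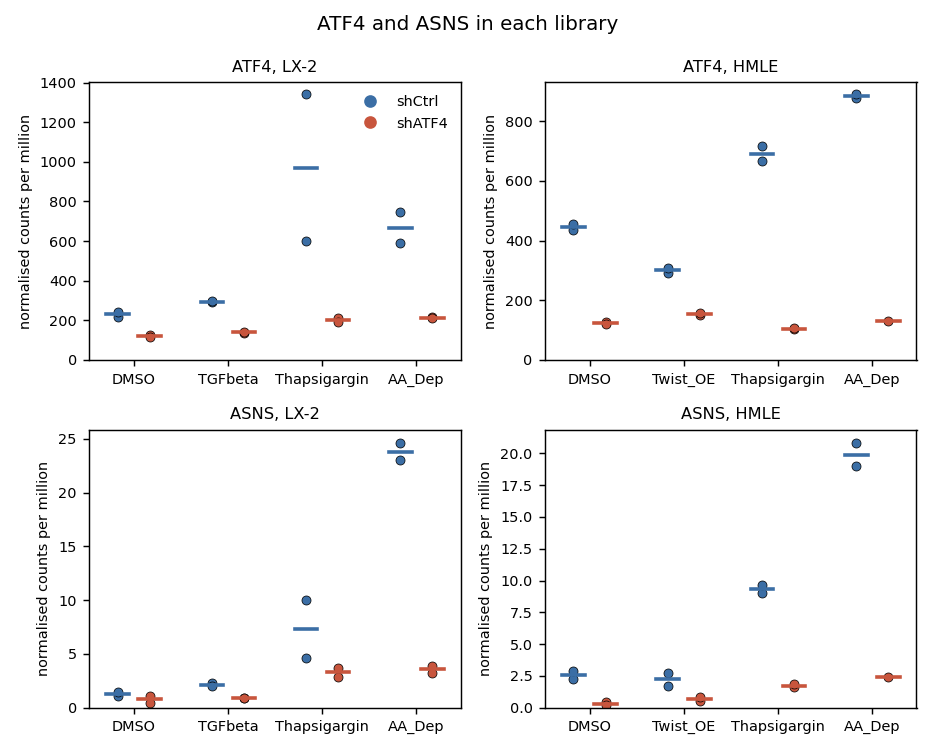
Normalised CPM of ATF4 and of its target ASNS (vertical axes, linear from 0) by condition in LX-2 (left) and HMLE (right); each point is 1 library and each bar the group mean, blue for shCtrl and red for shATF4. Mean ATF4 in HMLE AA_Dep was 885 with shCtrl and 129 with shATF4, and mean ASNS in LX-2 AA_Dep was 23.8 against 3.57.

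TGFbeta in LX-2 shCtrl cells raised the genes of the TGF-beta and SMAD response and the fibrillar matrix. Of the 17 measured genes of the TGF-beta and SMAD list, 15 rose and none fell, with a median log2 change of 2.14. PMEPA1, a feedback inhibitor of SMAD signalling, rose by 5.18 ± 0.20 (log2, SE; adjusted p = 5.9e-07), and the cell cycle inhibitor CDKN2B by 2.67. COL1A1, the main chain of collagen I, went from 4990 ± 148 to 16200 ± 161 normalised CPM (SD, n = 2; log2 change 1.70, adjusted p = 0.0002). COL1A2 rose by 2.31, COL5A1 by 1.65 and SPARC by 1.69 on the same scale. Among 25 collagens and matrix proteins 10 rose (16 when adjusted over the list alone) and none fell, with a median of 1.26.

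The largest rises under TGFbeta were those of FOXS1, NOX4 (an oxidase that makes hydrogen peroxide, log2 change 6.26), ISLR2 (6.08), GDF6 (5.84) and ACTBL2 (5.41). FOXS1 had 749 counts over both TGFbeta libraries and 1 over both DMSO libraries, a counting ratio of 830 (149 to 32800). The largest falls were those of MYPN (-4.97), SEMA3A (-3.99), CAVIN2 (-3.84) and BMP4 (-3.71), with PSG1, whose family members share reads, left aside as uncertain. MMP1, an interstitial collagenase, fell by 2.70 on the log2 scale. The smooth muscle actin gene ACTA2, chosen after its values were seen, moved from 30.7 ± 0.0579 to 50.8 ± 1.67 CPM (log2 0.73, adjusted p = 0.90 with all 16 libraries and 0.00038 with 15). Collagen-modifying enzymes rose (4 of 22, and 6 over the list alone, median 0.37), ER chaperones had a median of 0.39 (2 of 20 higher, camera 0.00016), and quiescent stellate cell markers fell (3 of 17, median -0.62, 7 lower over the list alone).

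By edgeR's quasi-likelihood test 270 genes were higher and 290 lower with TGFbeta among 17772 tested. Without the discordant library, which is in neither group, 2071 were higher and 2058 lower of 18649. Leaving out either DMSO or either TGFbeta library gave 154 to 168 genes. The camera test with Benjamini-Hochberg adjustment gave 3e-32 for the SMAD list, 5.7e-16 for collagens, 2.2e-07 for collagen-modifying enzymes and 0.00015 for quiescent markers, and with an estimated correlation between genes these were 0.0071, 0.027, 0.0071 and 0.028.

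**Figure D2:**
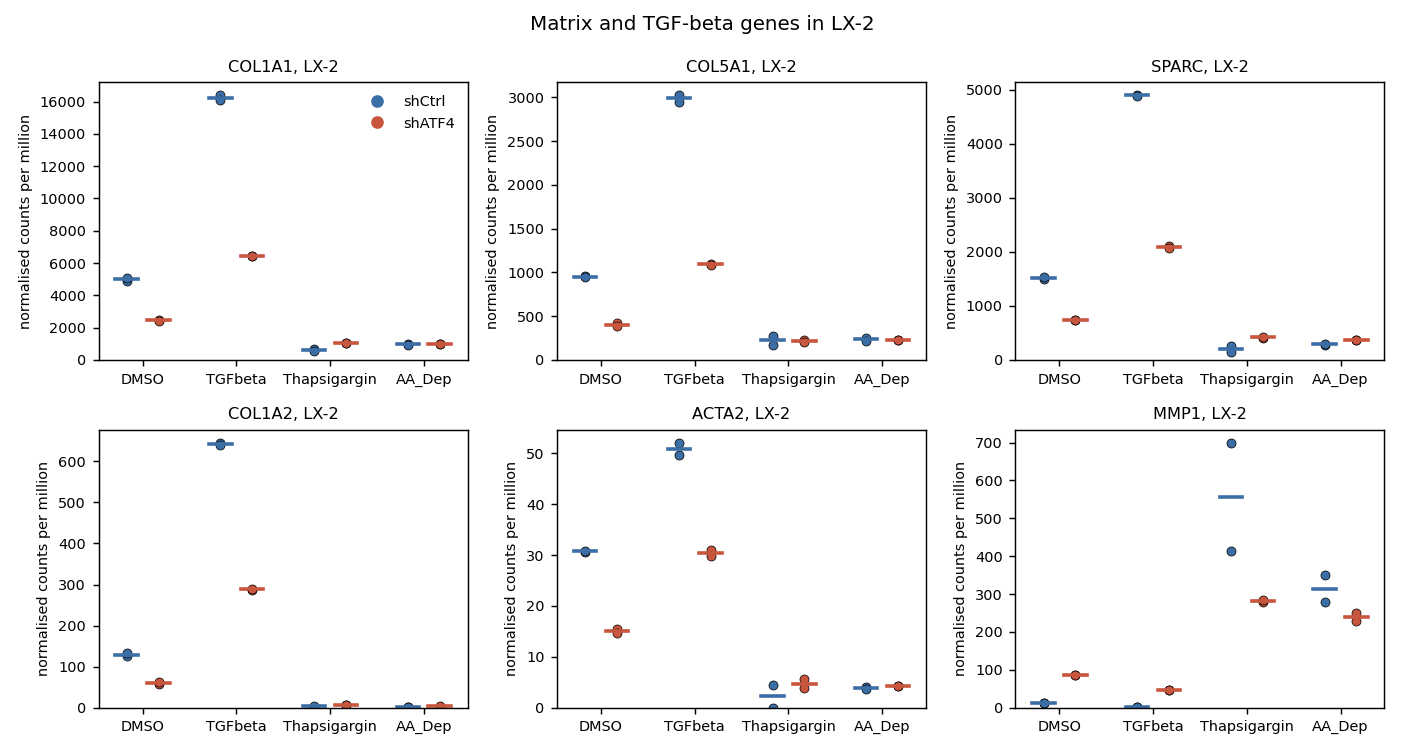
Normalised CPM (vertical axes, linear from 0) of 6 genes in LX-2 by condition; each point is 1 library and each bar the mean of 2, blue for shCtrl and red for shATF4. COL1A1 averaged 16200 in TGFbeta with shCtrl and 6430 with shATF4, and MMP1 averaged 1.98 and 46.0.

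In LX-2 shCtrl cells stress response and ER genes were higher with thapsigargin than in DMSO, and matrix genes lower. Of 19 integrated stress response targets 16 rose and none fell (17 rose over the list alone), with a median log2 change of 2.51. DDIT3, the stress transcription factor CHOP, rose by 7.25 ± 0.75 with all libraries and by 5.32 without the discordant one. TRIB3 rose by 4.07 and CHAC1, a glutathione-degrading enzyme, by 3.94. HSPA5, the main ER chaperone, went from 768 ± 8.30 to 12400 ± 1940 CPM, and 15 of 20 ER chaperone and ER-associated degradation genes rose (median 1.85). Genes of serine, glycine, one-carbon and proline synthesis rose in 11 of 16 (median 1.06). Of 25 collagens and matrix proteins 23 fell and none rose, with a median of -2.51: COL1A1 fell from 4990 to 621 CPM, COL1A2 by a log2 change of -5.35 and SPARC by -2.90. Contractile genes (10 of 15 lower, median -1.01), mesenchymal genes (11 of 18 lower) and cell cycle genes (14 of 24 lower, median -0.96) fell too, and MMP1 rose by 5.43.

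Some LX-2 genes were found in 1 of the 2 conditions alone. Over the group, with 3 counts as the floor, SMOC1 and TENM4 were at least 101-fold higher in thapsigargin, whereas ITGB6 was at least 118-fold and CD248 at least 107-fold lower. IGFBP5, an IGF-binding protein, fell by 10.63 on the log2 scale (adjusted p = 4.3e-06), and by 9.92 without the discordant library. Shifts of neighbouring genes accompanied these changes: over 130 windows of at least 100 neighbouring genes, the window medians of the log2 change had an SD of 0.21, against at most 0.0896 in 100 shuffles of positions.

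With all libraries 3427 genes were higher and 2679 lower, and without the discordant library 3760 and 3798. With only the compared groups in the fit edgeR called 0 (1750 at an unadjusted p under 0.05). Without shCtrl thapsigargin replicate 1 the count was 14086, and without DMSO replicate 1 or 2 it was 1676 or 1903. Adjusted camera p was 2.4e-11 for stress response targets, 7.9e-12 for ER chaperones, 1.8e-05 for serine and related synthesis and 2.6e-13 for collagens. Ribosomal protein genes were higher in 20 of 25 with all libraries (median 1.70, camera 3e-05, 0.44 with an estimated correlation), but 4 were higher and 2 lower without the discordant library (median 0.22, 0.24).

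In LX-2 shCtrl cells amino acid and stress response genes were higher in AA_Dep than in DMSO, and matrix and cholesterol genes lower. Of 19 integrated stress response targets 14 rose (17 over the list alone), with a median log2 change of 2.10. ASNS, the asparagine synthetase, went from 1.26 ± 0.315 to 23.8 ± 1.14 CPM (log2 4.23, adjusted p = 0.00015), CHAC1 rose by 4.04 and TRIB3 by 2.43. HSPA5 fell by 0.70 on the log2 scale. Amino acid transporters rose in 4 of 12 (median 0.63) and 13 of 21 cholesterol synthesis genes fell (median -0.76), among them INSIG1 (-1.17). Collagens and matrix proteins fell in 17 of 25 (22 over the list alone, median -1.98), with COL1A1 at 965 ± 54.6 CPM and COL1A2 at 0.64 ± 0.109 against 129 ± 4.85 in DMSO. Contractile genes fell in 8 of 15 (median -1.24), whereas MMP1 rose by 4.61.

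NLGN4X was at least 179-fold higher in AA_Dep, TENM4 and SMOC1 at least 89.9-fold, and the long noncoding RNA UCA1 rose by 8.26. MSTN was at least 173-fold lower, B3GALNT1 at least 102-fold lower, and IGFBP5 fell by 9.02. As in thapsigargin, windows of neighbouring genes moved together, with an SD of window medians of 0.216 against at most 0.0828 in shuffles; between AA_Dep and thapsigargin directly the SD was 0.0896. Smaller excesses over shuffles were found elsewhere, such as 0.108 against at most 0.0513 in LX-2 TGFbeta, 0.125 against 0.0546 for shATF4 in LX-2 TGFbeta and 0.134 against 0.0988 in HMLE AA_Dep. There were 1083 genes higher and 1235 lower with all 16 libraries, and 4261 and 4235 with 15. Leaving out either DMSO or either AA_Dep library gave 894 to 1115. By camera, adjusted p was 1.2e-14 for stress response targets, 1.1e-17 for collagens, 3.3e-09 for cholesterol synthesis and 1.4e-05 for contractile genes.

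**Figure D3:**
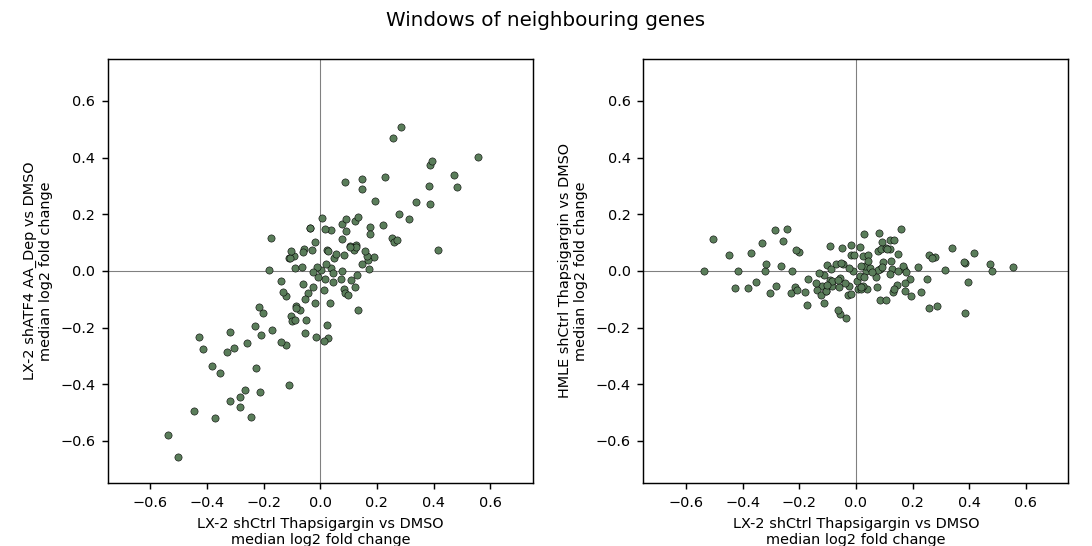
Each point is 1 of 130 windows of neighbouring genes, placed by its median log2 change in LX-2 shCtrl thapsigargin against DMSO (horizontal axes) and in LX-2 shATF4 AA_Dep (left) or HMLE shCtrl thapsigargin (right) against DMSO (vertical axes). Across windows, which are not independent replicates, the correlation was 0.83 on the left and 0.01 on the right.

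The LX-2 thapsigargin and AA_Dep responses had 663 genes higher in both and 839 lower in both, against 209 and 186 for independent lists. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.62 (covariance 1.34). Simulated unchanged groups against the same DMSO libraries gave r = 0.48, a covariance of 0.186 and a mean of 0 genes called in the same direction. Sharing DMSO libraries thus fell short of the observed covariance in these simulations, though it may add part of it. Responses with separate DMSO libraries were not compared gene by gene. TGFbeta and thapsigargin had 49 genes higher in both and 104 lower in both against 52.1 and 43.7, and in opposite directions 111 (higher with TGFbeta) and 62 against 40.7 and 55.9 (covariance -0.0213, simulated 0.188). TGFbeta and AA_Dep had 67 and 60 against 16.5 and 20.2, and in opposite directions 53 and 66 against 18.8 and 17.7 (covariance 0.0876, simulated 0.188). Neither comparison of covariances was stable: without the discordant library that with thapsigargin was 0.0909 (simulated 0.119), its sign turned, with 511 and 734 genes moving together and 664 and 455 apart, and that with AA_Dep was 0.129 (simulated 0.118).

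In unstressed LX-2 cells (DMSO) matrix genes were lower and MMP1 higher with shATF4 than with shCtrl. The labels name no other hairpin against ATF4, so effects of this hairpin or of these cells apart from ATF4 were not separated. COL1A1 fell from 4990 ± 148 to 2460 ± 26.8 CPM (log2 -1.02, adjusted p = 0.029), COL1A2 by a log2 change of -1.10 and COL5A1 by -1.24. Of 25 collagens and matrix proteins 3 fell over all genes and 11 over the list alone, where 1 rose (median -0.88). MMP1 rose from 12.9 ± 0.546 to 85.7 ± 0.417 CPM (log2 2.73), ESM1 by 2.33 and the nerve growth factor receptor NGFR by 2.31. DDIT4, a stress-induced inhibitor of mTORC1, fell by 1.8 and PMEPA1 by 1.47. The other stress response targets did not pass with all libraries. Among them ATF3 had a log2 change of 1.15 and DDIT3 one of 0.87, and both rises passed without the discordant library (edgeR adjusted p = 0.00021 and 0.00055). CHAC1 stood at 3.74 CPM with shATF4 against 4.9, and TRIB3 at 32.4 against 36.3. Hypoxia and glycolysis genes had a median of -0.45 and cholesterol synthesis genes one of -0.22, each with no member past the edgeR threshold over all genes; unadjusted, 1158 of all genes had p under 0.05, and DESeq2 called 353. Totals were 21 genes higher and 22 lower with all libraries, and 1171 and 989 without the discordant library. Leaving out any DMSO library of either hairpin left 7 genes or fewer. Adjusted camera p was 4.3e-15 for collagens, 5.6e-06 for matrix proteases (1 of 11 higher, median 0.56) and 1.9e-05 for hypoxia and glycolysis.

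In TGFbeta-treated LX-2 cells shATF4 lowered the same kinds of genes from a higher level. COL1A1 stood at 6430 ± 33.3 CPM against 16200 ± 161 (log2 -1.34, adjusted p = 0.0018). COL5A3 fell by 2.01, COL5A1 by 1.45, COL1A2 by 1.15 and SPARC by 1.23, and CDKN2B by 2.42. Of the collagens and matrix proteins 6 of 25 fell (9 over the list alone, median -0.89), and of the TGF-beta and SMAD list 2 of 17 (5 over the list alone, median -0.76). MMP1 rose from 1.98 ± 0.415 to 46.0 ± 0.357 CPM (log2 4.53, adjusted p = 9.6e-05), FST, an activin-binding protein, by 3.24, ESM1 by 3, PTX3 by 2.77 and the chemokine CXCL8 by 2.70. KCNE4 (-3.37), MEGF6 (-2.69), KIF26B (-2.68) and DDIT4 (-2.62) were among the largest falls.

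In that comparison 115 genes were higher and 114 lower with all libraries, and 2042 and 2002 without the discordant library. Leaving out any of the 4 compared libraries gave 38 to 46. By camera, adjusted p was 1.8e-10 for collagens, 1.9e-06 for the SMAD list and 0.0001 for inflammatory cytokines (4 of 18 higher, median 0.83). With an estimated correlation none of these passed (0.073, 0.13 and 0.15). Of 43 genes changed by shATF4 in DMSO, 19 were also higher and 19 also lower in TGFbeta, against 0.136 and 0.141 for independent lists, with no library shared. Both comparisons set shATF4 against shCtrl cells, so any fixed difference between these cells would recur in both. Genes that rose with TGFbeta and fell with shATF4 numbered 44, and those that fell and rose numbered 48, against 1.73 and 1.88. The shared shCtrl TGFbeta libraries alone gave a simulated covariance of -0.195 where -0.205 was observed, so part of that opposition may come from them. That simulation used a spread widened by the discordant library, which is in none of the groups compared. Without that library the covariance was -0.252 against a simulated -0.13.

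Whether shATF4 changed the TGFbeta response itself was tested as an interaction. With all 16 libraries edgeR called 0 genes (353 at an unadjusted p under 0.05), and DESeq2 called 36. Without the discordant library 105 genes had a higher and 79 a lower response. For collagens and matrix proteins the median shATF4 changes given above were alike in DMSO and in TGFbeta. List medians with all libraries were 0.36 for cholesterol synthesis (camera 4.7e-07), -0.30 for the SMAD list, -0.25 for stress response targets and 0.11 for inflammatory cytokines (0.00012 each). With an estimated correlation these were 0.019, 0.32, 0.054 and 0.28.

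In thapsigargin, LX-2 shATF4 cells had lower stress response genes than shCtrl cells. Of 19 integrated stress response targets 5 fell (14 over the list alone) and none rose, with a median log2 change of -1.24. TRIB3 fell by 2.00, CHAC1 by 1.87 and HSPA5 by 1, and NUPR1 by 4.38 (by a log2 change of -2.17 without the discordant library). Serine, glycine, one-carbon and proline synthesis had a median of -0.77, with 10 of 16 lower over the list alone. By edgeR 5735 of 17772 genes had an unadjusted p under 0.05 here, so a low p was not particular to these lists. Without the discordant library PHGDH went from a log2 change of -2.65 to -0.92, and SHMT2 from -1.81 to -1.03. The complement gene C3 rose by 2.17, DUSP10 by 1.91 and NGFR by 1.83. Over all genes the median change was 0.15 with all libraries and 0.01 without the discordant one. There were 24 genes higher and 17 lower with all libraries, 580 and 389 without the discordant library and 13731 in all without its replicate. With only the compared groups in the fit edgeR called 0 (215 unadjusted); without shATF4 thapsigargin replicate 1 or replicate 2 edgeR called 0 genes (3549 and 3003 at an unadjusted p under 0.05), whereas DESeq2 with all libraries called 4197. Adjusted camera p was 2.4e-09 for stress response targets.

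In AA_Dep, LX-2 shATF4 cells had lower amino acid and stress response genes. ASNS fell from 23.8 ± 1.14 to 3.57 ± 0.481 CPM (log2 -2.73, adjusted p = 0.036), CHAC1 by a log2 change of -2.66 and the amino acid transporter SLC7A5 by -2.51 (0.0049 each), TRIB3 by -1.91 and DDIT4 by -1.75. Of 19 stress response targets 5 fell (12 over the list alone, median -1.13), and medians were -0.77 for amino acid transporters (1 of 12 lower, 7 over the list alone, camera 5.9e-12), -0.72 for serine and related synthesis (0 of 16, 5 over the list alone, 1.2e-08) and -0.54 for aminoacyl-tRNA synthetases (1 of 20, 2 over the list alone, 5.5e-07). INSIG1 (1.03), MSMO1 (1.31), NGFR (1.39) and the antiviral sensor DHX58 (1.75) rose. Cholesterol synthesis genes had a median of 0.67 (2 of 21 higher, 15 over the list alone), and 14 of 21 interferon response genes were higher over the list alone (median 1.73). None of those 21 passed over all genes with 16 libraries, where 932 of all genes had an unadjusted p under 0.05, and 19 passed with 15 libraries. IFIT1 stood at 64.8 ± 33.2 against 11.4 ± 3.42 CPM. Totals were 6 genes higher and 10 lower with all libraries, against 222 in all by DESeq2, and 722 and 1127 without the discordant library; leaving out any AA_Dep library of either hairpin left 4 or fewer. By camera, adjusted p was 7.3e-28 for stress response targets, 9.5e-25 for cholesterol synthesis and 1.4e-26 for interferon genes. These values rest on the preset correlation of 0.01, which counts members of a list as nearly independent. Interferon genes varied widely between the shATF4 libraries, as IFIT1 shows, so their value overstates the certainty.

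Differences in the stress responses between hairpins were tested as interactions. The interaction with thapsigargin was positive for collagens and matrix proteins (4 of 25 higher, 13 over the list alone, median 1.48, camera 2.9e-09, 0.083 with an estimated correlation), with COL1A2 at 2.20 and MMP1 at -3.71 on the log2 scale. With AA_Dep the same list had a median of 0.80 (1 of 25 higher, 5 higher and 1 lower over the list alone, 2.6e-10), COL1A2 a value of 3.29, MMP1 one of -3.12 and SLC7A5 one of -2.29. Stress response targets had medians of -1.48 (2 of 19 lower, 11 over the list alone) and -1.34 (0 of 19, 9 over the list alone). COL1A1 in thapsigargin stood at 1050 ± 19.8 with shATF4 against 621 ± 95.9 CPM, and in AA_Dep at 984 ± 18.5 against 965 ± 54.6. The thapsigargin interaction had 31 genes higher and 17 lower with all libraries and 684 and 459 without the discordant one, and 0 (768 unadjusted) with only the compared groups in the fit; without its replicate it had 12126, and without any of the other 6 libraries at most 1. The AA_Dep interaction had 4 and 8 genes, then 730 and 1241 without the discordant library, and at most 3 without any of the 8 compared libraries.

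**Figure D4:**
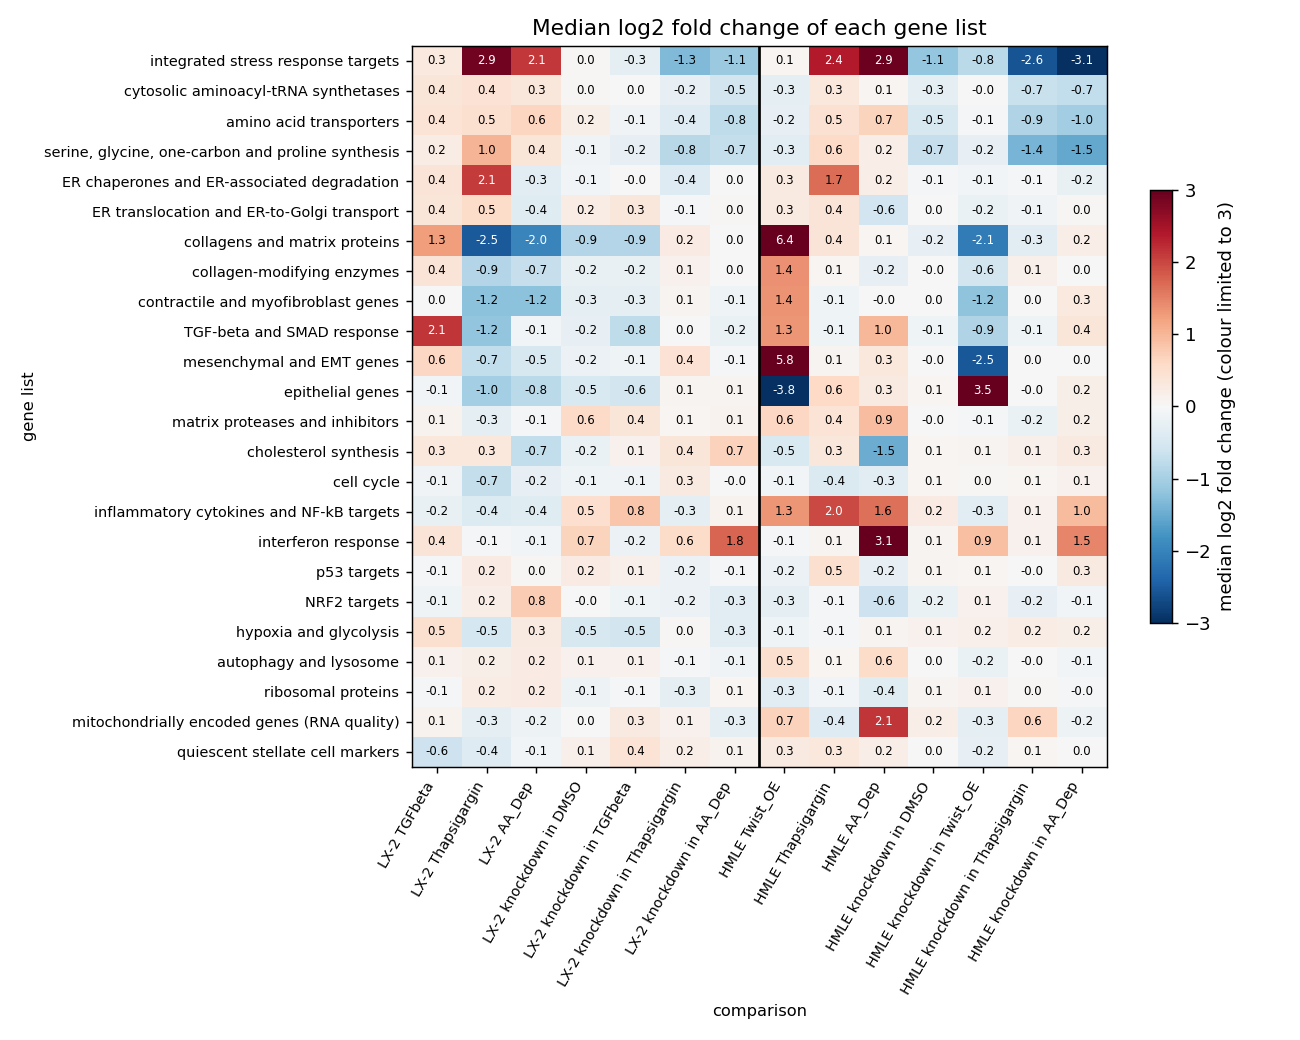
Median log2 fold change (colour, limited to 3, and printed value) of each gene list (vertical axis) in each comparison (horizontal axis), LX-2 left of the line and HMLE right of it, LX-2 without the discordant library. Collagens and matrix proteins had medians of -0.87 and -0.88 with shATF4 in LX-2 DMSO and TGFbeta, and of -2.10 in HMLE Twist_OE.

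Twist_OE in HMLE shCtrl cells exchanged epithelial for mesenchymal expression. TWIST1 rose from 16.7 ± 0.349 to 130 ± 9.99 CPM (log2 2.96 ± 0.11, adjusted p = 3.2e-14), and TWIST2, chosen after its values were seen, from 3.27 and 3.72 to 19.8 and 20.2 CPM. CDH1, the epithelial cadherin, fell from 538 ± 7.39 to 20.3 ± 2.58 CPM, while the neural cadherin CDH2 rose from 4.30 ± 0.112 to 204 ± 10.8. VIM rose by 7.56 on the log2 scale, ZEB1, a repressor of epithelial genes, by 8.74 and FN1 by 5.15. Of 18 mesenchymal and EMT genes 17 rose (median 5.84), and of 29 epithelial genes 28 fell (median -3.81). With genes absent in 1 group at their bound, and genes with at most 3 counts in the higher group left out, the mesenchymal median was 6.12. Collagens and matrix proteins rose in 21 of 24 (median 6.41, 5.73 by that rule), with COL1A1 at 1210 ± 51.7 against 12.6 ± 1.01 CPM. Of the SMAD list 15 of 16 genes were higher (median 1.32).

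HHIP, an inhibitor of hedgehog signalling, was at least 1920-fold higher in Twist_OE, DCN at least 1060-fold, CDH11 at least 559-fold, PRRX1 at least 538-fold and ROR2 at least 444-fold (floor of 3 counts over the group). Among the largest falls were those of S100P (-7.66), CALB2 (-7.50), KRT13 (-7.46) and BSPRY (-7.20). ATF4 fell by 0.57 on the log2 scale and TRIB3 by 1.43. Aminoacyl-tRNA synthetases fell in 16 of 20 (median -0.28), and all 25 ribosomal protein genes fell slightly (median -0.31). In total 5083 genes were higher and 5176 lower, of which 2418 and 1531 moved at least 2-fold. Adjusted camera p was 1.3e-19 for epithelial genes, 3.9e-12 for mesenchymal genes and 1.6e-12 for collagens.

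Knockdown of ATF4 in Twist_OE cells went with epithelial genes near their DMSO levels and lower mesenchymal genes. CDH1 stood at 517 ± 32 CPM with shATF4 (log2 4.67 against shCtrl, adjusted p = 4.5e-19), beside 538 in shCtrl DMSO. KRT5 rose by 3.48, LCN2 by 6.90, TJP3 by 6.69 and KRT13 by 6.41. VIM fell by 2.53, CDH2 by 1.94, ZEB1 by 2.94 and COL1A1 by 3, while CMKLR1 (-4.65), BGN (-4.33), MGP (-4.11) and SDC2 (-4.09) were among the largest falls. Of 29 epithelial genes 28 rose (median 3.48), and 17 of 18 mesenchymal genes (median -2.55) and 21 of 24 collagens (median -2.10) fell. TWIST1 itself was lower, at 30.4 ± 0.328 CPM against 130 ± 9.99 (log2 -2.09, adjusted p = 4.1e-12), and TWIST2 stood at 6.51 and 6.41 CPM.

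There were 4174 genes higher and 4286 lower. By camera, adjusted p was 4.5e-26 for epithelial genes, 4.9e-10 for mesenchymal genes and 2.6e-08 for collagens. Genes raised by Twist_OE and lower with shATF4 numbered 3550, and those lowered and then higher 3480, against 1210 and 1200 for independent lists (across genes r = -0.80, covariance -1.55; simulated -0.51 and -0.134). Part of that excess may come from the shared shCtrl Twist_OE libraries. The interaction of shATF4 with Twist_OE had 2929 genes higher and 2399 lower: LCN2 (7.07) and KRT13 (6.41) were at the upper end and MGP (-4.89) at the lower, and epithelial genes had a median of 3.78 (27 of 29 higher, camera 5.7e-31).

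**Figure D5:**
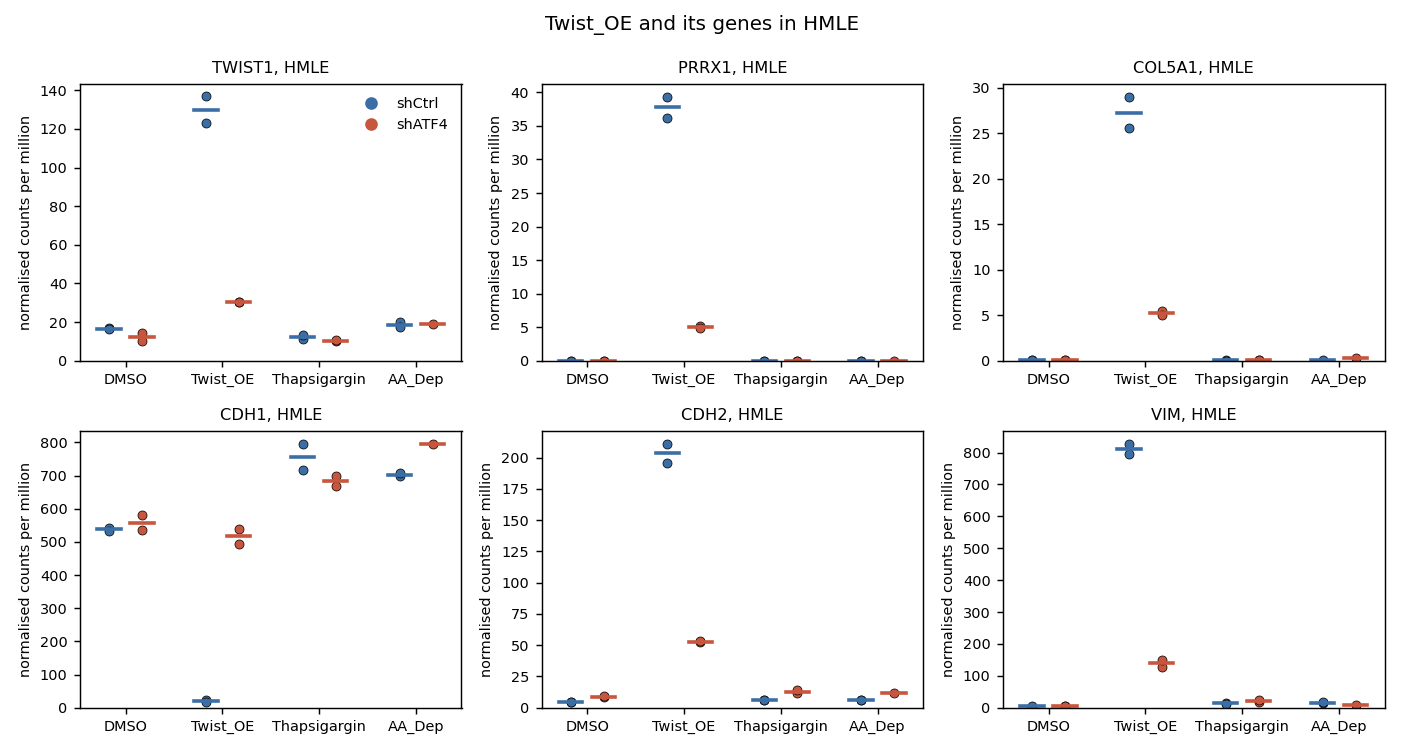
Normalised CPM (vertical axes, linear from 0) of 6 genes in HMLE by condition; each point is 1 library and each bar the group mean, blue for shCtrl and red for shATF4. In Twist_OE, CDH1 averaged 20.3 with shCtrl and 517 with shATF4, and TWIST1 130 and 30.4.

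Thapsigargin in HMLE shCtrl cells raised stress response, ER chaperone and inflammatory genes. DDIT3 went from 3.51 ± 0.319 to 127 ± 1.11 CPM (log2 5.17, adjusted p = 2.6e-16), HSPA5 from 1250 ± 3.06 to 9260 ± 434, and CHAC1 rose by 3.82. Of 20 stress response targets 19 rose and 1 fell (median 2.38), and all 19 measured ER chaperone genes rose (median 1.68). Inflammatory cytokines and NF-kB targets rose in 17 of 19 (median 1.97), with CXCL8, a neutrophil chemokine, at 5.14 and the transcription factor NFATC2 at 5.16. Cell cycle genes fell in 21 of 24 (median -0.43). TNFRSF10D (-3.40) and EGR1 (-2.60) were among the largest falls. There were 3336 genes higher and 3263 lower, and camera gave 9.8e-16 for stress response targets, 1.4e-21 for ER chaperones, 7.5e-14 for inflammatory genes and 3.6e-10 for the cell cycle.

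In HMLE shCtrl cells stress response and interferon genes were higher in AA_Dep than in DMSO, and cholesterol synthesis genes lower. ASNS went from 2.58 ± 0.450 to 19.9 ± 1.24 CPM and CHAC1 from 10.9 ± 0.222 to 162 ± 13.6, and 19 of 20 stress response targets rose (median 2.93). All 21 cholesterol synthesis genes fell (median -1.48), including HMGCS1 (-2.04) and INSIG1 (-1.72). Interferon response genes rose in 19 of 21 (median 3.06), with RSAD2 at 5.69, IFIT1 at 4.39 and ISG15 at 3.30, and inflammatory genes in 17 of 19 (median 1.65). CYP1A1 (-4.80) and CYP1B1 (-2.97), both induced through the aryl hydrocarbon receptor, were among the largest falls. The AA_Dep libraries stood apart in their mitochondrially encoded RNA, 2.538% to 2.946% of counts against 0.366% to 0.969% in the other HMLE libraries (12 of 13 genes higher, median 2.15). Their total counts, 15956909 to 16964896, were also below the 19802962 to 23243132 of the other HMLE libraries. A difference of these libraries or cells from the others cannot be told apart from an effect of AA_Dep. Totals were 5225 genes higher and 5841 lower. Adjusted camera p was 3.4e-11 for stress response targets, 5.5e-12 for cholesterol synthesis and 1.6e-10 for interferon genes. Thapsigargin and AA_Dep in HMLE had 1750 genes higher in both and 2083 lower in both, against 972 and 1060 (covariance 0.352, simulated 0.132), and part of that excess may come from the shared DMSO libraries.

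Without stress, shATF4 in HMLE lowered amino acid synthesis genes. PSAT1 fell from 438 ± 0.985 to 143 ± 1.31 CPM, PHGDH, the first enzyme of serine synthesis, by a log2 change of -1.77, ALDH1L2 by -2.55 and CHAC1 by -3.70, and the protease PAPPA2 by -4.45. Of 16 serine, glycine, one-carbon and proline synthesis genes 12 fell and 1 rose (median -0.68), as did 11 of 20 aminoacyl-tRNA synthetases (median -0.30), 9 of 13 amino acid transporters (median -0.47) and 12 of 20 stress response targets (median -1.15, -0.78 with genes at their bound). Under the rule for named genes, with its minimum of 5 CPM, ADAMTS12 (1.82) and CXADR (1.77) rose most among genes with no near-identical copy. AMOT stood at 5.29 ± 0.701 CPM with shATF4 against 1 ± 0.283 in the fit of both lines. Totals were 1090 higher and 1205 lower, and leaving out any DMSO library of either hairpin gave 1101 to 1470 genes. By camera, adjusted p was 1.9e-13 for serine and related synthesis, 4.1e-09 for stress response targets and 1.9e-08 for synthetases.

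In stressed HMLE cells shATF4 lowered stress response targets. In thapsigargin 18 of 20 stress response targets fell with shATF4 (median -2.59): CHAC1 by a log2 change of -3.79, TRIB3 by -2.76 and SESN2 by -2.10, whereas HSPA5 fell by 0.38. Serine and related synthesis fell in 13 of 16 (median -1.40), and the matrix protease ADAMTS1 rose by 2.55. In AA_Dep, from 1 shATF4 library, 17 of 20 targets fell (median -3.06), CHAC1 by -4.50, ASNS by -3.05 and PSAT1 by -2.91. All 21 interferon response genes were higher (median 1.47), MX2 by 4.10, IFITM1 by 3.98 and IFI27 by 3.25, and 15 of 19 inflammatory genes (median 0.96). The thapsigargin comparison had 2212 genes higher and 2141 lower and that in AA_Dep 1753 and 1272. Camera gave 5.9e-21 and 1.2e-20 for stress response targets, and 1.2e-21 for interferon genes in AA_Dep.

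Both stress interactions in HMLE held stress response targets at a negative median, -0.86 for thapsigargin (10 of 20 lower) and -1 for AA_Dep (9 of 20 lower; camera 4e-19 and 7.4e-18). In thapsigargin TRIB3 had an interaction of -1.98 and SESN2 one of -2.12, and in AA_Dep DDIT4 one of -2.80 and TRIB3 one of -2.37. IFI27 (4.01), IFI6 (3.23) and MX1 (3.17) were at the upper end in AA_Dep, where 16 of 21 interferon genes were higher (median 0.94). There were 388 genes higher and 430 lower for thapsigargin, with 499 in all without shATF4 DMSO replicate 2, 515 without shCtrl DMSO replicate 2 and 544 without shCtrl thapsigargin replicate 2. For AA_Dep there were 537 and 377, with 577 without shCtrl AA_Dep replicate 1 and 603 without shCtrl DMSO replicate 2.

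Set against each other, the lines differed in matrix and inflammatory responses to stress. Collagens and matrix proteins fell in LX-2 relative to HMLE in thapsigargin (18 of 25, median difference -3.17) and in AA_Dep (13 of 25, -2.15). DMSO levels of COL1A1 were 4990 CPM in LX-2 and 12.6 in HMLE. Some of these genes were near the floor in HMLE, with little room to fall there. COL1A2 stood at 0 CPM in HMLE shCtrl DMSO, and COL3A1 and COL6A2 at 0.178 and 0.239 in HMLE shCtrl AA_Dep. Inflammatory genes differed by a median of -3.19 in thapsigargin (14 of 19 lower) and -1.92 in AA_Dep (12 of 19), and interferon genes by -2.74 in AA_Dep (13 of 21). CCL5, CXCL8 and IFIT1 were among the genes that rose in HMLE AA_Dep without a rise in LX-2: IFIT1 had log2 changes of 4.39 and -0.31. The response to thapsigargin differed for 2328 genes upward and 2132 downward, and that to AA_Dep for 1387 and 1605; without the discordant library these were 2597 and 3033, and 4264 and 3912. With only the compared groups in the fit they were 35 and 6165 in all. Leaving out shCtrl thapsigargin replicate 1 of LX-2 gave 12171 for thapsigargin, and leaving out LX-2 DMSO replicate 1, HMLE DMSO replicate 2 or either HMLE thapsigargin library gave 2451 to 2847. Camera gave 1e-15 and 4.2e-12 for collagens, 7.6e-11 and 1.6e-11 for inflammatory genes, and 4.2e-12 for interferon genes. The thapsigargin responses shared 811 genes higher and 853 lower (independent 611 and 482; across genes r = 0.10), and the AA_Dep responses 508 and 503 (265 and 381; r = 0.12), with no library in common.

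The effect of shATF4 also differed between lines. In DMSO stress response targets differed by a median of 1.01 (LX-2 minus HMLE, 3 of 20 higher and 1 lower, camera 2.8e-13). CHAC1 differed by 3.30 and the AP-1 family repressor JDP2 by 2.56, but DDIT4 by -1.54 (adjusted p = 0.042). MMP1 differed by 3.29, though it was near the floor in HMLE, at 0.367 CPM with shATF4 and 0.552 with shCtrl. Collagens and matrix proteins differed by -0.76 (camera 2e-07, 0 of 25 past the threshold, 4 lower and 1 higher over the list alone). In AA_Dep the same targets differed by 1.28 (4 of 20 higher, 2.6e-13), inflammatory genes by -0.74 (2 of 19 lower, camera 1e-06, 0.063 with an estimated correlation) and TGF-beta and SMAD genes by -0.59 (2 of 17 lower, 1.2e-06 and 0.093). Counts were 45 higher and 31 lower in DMSO, 350 and 1013 in thapsigargin, and 35 and 42 in AA_Dep; without the discordant library they were 634 and 642, 693 and 487, and 578 and 878. For thapsigargin edgeR called 0 (718 unadjusted) with only the compared groups in the fit. For the DMSO comparison each of the other 8 compared libraries left out gave 26 to 40 genes, for thapsigargin the other 6 gave 56 to 83 except 11856 without shCtrl replicate 1 of LX-2, and for AA_Dep 5 of the others gave 32 to 40. TGFbeta in LX-2 and Twist_OE in HMLE shared 153 genes higher and 66 lower (independent 74.4 and 72; across genes r = 0.02), and 59 and 131 moved in opposite directions (70.5 and 76), the 131 lower with TGFbeta. The shATF4 effects in those conditions shared 33 and 59 (24.3 and 27.9; r = 0.05), with 46 and 29 opposite (27.9 and 24.3). In AA_Dep the shATF4 effects shared 4 and 9 genes of the 16 called in LX-2.

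Several other gene groups moved as well. Genes of ER translocation and ER-to-Golgi transport rose in 17 of 21 in HMLE thapsigargin (median 0.39, camera 5.9e-08, 0.063 with an estimated correlation) and fell in 19 of 21 in HMLE AA_Dep (median -0.58, 1.8e-06 and 0.13). NRF2 targets, which defend against oxidants, fell in 12 of 14 in HMLE AA_Dep (median -0.62, 0.00032 and 0.2), where autophagy and lysosome genes rose in 12 of 18 (median 0.55, 0.0043 and 0.27). The p53 targets rose with shATF4 in HMLE AA_Dep (10 of 19, median 0.28, 0.00013 and 0.024). Mitochondrially encoded genes rose in 13 of 13 with shATF4 in HMLE thapsigargin (median 0.64, 6.8e-06 and 0.39). Among endothelial markers 6 were measured in LX-2 (median 0.20 in TGFbeta, camera 0.53), while fewer than 5 hepatocyte and leukocyte markers passed the count filter, so neither list was tested.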

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

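All 11 tests that weigh explanations below were chosen only after the results were seen. The interactions given first were planned. In LX-2 the response to thapsigargin differed between hairpins for 48 genes, and that to AA_Dep for 12. In HMLE the response to Twist_OE differed for 5328 genes, that to thapsigargin for 818 and that to AA_Dep for 914. Between lines, the shCtrl responses differed for 4460 genes in thapsigargin and 2992 in AA_Dep, and the effect of shATF4 for 76 in DMSO, 1363 in thapsigargin and 77 in AA_Dep.

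LX-2 shCtrl thapsigargin replicate 2 lay far from its replicate. Replicate 1 thinned to its depth still had counts for 23688 genes against 15840, which argues against depth. Its highest correlation with an HMLE library was 0.655 against at least 0.701 with every library of the other LX-2 groups, which argues against an HMLE library. The earlier correlation, 0.803 with its replicate, was taken within LX-2 alone, and there its lowest value with a library of another group was 0.68. Markers of 3 other cell types summed to at most 0.395 of the highest other library, which argues against RNA of those cells. Its ratio to each LX-2 group without thapsigargin was higher for ER chaperones than for genes of the same level (at most 0.02% of 10000 draws as high), which argues against a library of those groups. Against shATF4 thapsigargin 9 stress response targets had a median log2 ratio of 0.403 (1.02% of draws as high), which argues less strongly against that group. The share of genes nearer to replicate 1 than to another group, 37.9% to 96%, decides nothing, as lost transcripts move it. Its mitochondrially encoded RNA was 0.154% of counts against 2.037% to 3.14% in the other LX-2 libraries. Only 2.13% of its detected genes had 1 or 2 counts, against 17.1% to 18.9% elsewhere, as fewer captured molecules would leave. Of 3145 genes changed at least 2-fold by thapsigargin in the fit without it, 78.5% moved the same way in it. A sample from outside the series stays open, and no biological explanation was tested.

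In HMLE shATF4 cells the Twist_OE response was smaller. On the linear CPM scale, genes raised at least 2-fold kept a median of 25.4% of their rise (quartiles 14.3 and 41.2), and TWIST1 itself kept 16%. These shares are not shares of the log2 changes given above. A need for ATF4 downstream of Twist therefore cannot be told apart from less Twist in these libraries. The same effect of shATF4 without Twist_OE is argued against for 1296 genes lowered by Twist_OE and higher with shATF4. Their log2 change with shATF4 in DMSO was a median of -0.238% of that in Twist_OE. By their choice these genes were higher in DMSO than in Twist_OE, so a rise may have had less room there. Genes raised by Twist_OE were not put to this test.

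In LX-2, genes in the same neighbourhood moved together in thapsigargin and AA_Dep. In shCtrl cells the SD of window medians was at least 0.21, above every shuffle, which argues against chance placing, and the correlation with HMLE windows was at most 0.02, which argues against an effect in any stressed cell. Thapsigargin in shCtrl and AA_Dep in shATF4 cells, which shared no library, correlated at 0.83 across windows, against 0.3 for AA_Dep in shCtrl and thapsigargin in shATF4 HMLE cells, 0.84 for AA_Dep in both HMLE hairpins and -0.41 for LX-2 TGFbeta with shATF4 AA_Dep, so cells with another DNA copy number than the DMSO cells are a candidate explanation; an effect of stress in LX-2 alone stays open. The HMLE AA_Dep profiles of both hairpins shared no library either, so the same candidate stays open there. After window medians were removed from the fit without the discordant library, the collagen median in thapsigargin went from -2.51 to -2.42 and that of stress response targets from 2.9 to 2.86. This removal takes out only shifts shared by neighbouring genes. It cannot show whether matrix genes differ because of stress or because the cells differed from the DMSO cells.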

How the results depend on the processing

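The LX-2 counts rest on 1 library. The fit without LX-2 shCtrl thapsigargin replicate 2 was chosen only after the data were seen for comparisons that do not hold that library, as was the removal of window medians. With that library the common dispersion of LX-2 was 0.0872, and without it 0.00848. Counts in comparisons that never used it rose when it was left out. The tested genes also went from 17772 to 18649, and the share of each in the rise was not tested. Of the 104 LX-2, 87 HMLE and 4 between-line results for named genes, none changed direction while past the threshold under the alternatives run for it. Of those in LX-2, 45 lost the threshold when at least 1 of the compared libraries was left out, 25 when only the compared groups were fitted, 11 with the replicate block and 3 with no count filter. In HMLE 0 lost it under these alternatives, and between lines 2 did when a library was left out and 1 with the replicate block. With 2 libraries per group, leaving 1 out leaves a lone library that is assumed to vary like the other groups. In simulated data with 16 LX-2 libraries 60.6% of 66 genes with a log2 change of 2 were found, and 1.49% of 67 with 1, so genes not called there are not shown to be unchanged. The median of all genes shifted by 0.15 for shATF4 in LX-2 thapsigargin, 0.11 for the LX-2 thapsigargin interaction, -0.14 for the thapsigargin response between lines and 0.15 for the shATF4 effect in thapsigargin between lines.

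Leaving out 1 library at a time, the count of changed genes in LX-2 ran from 154 to 4129 for TGFbeta, 1676 to 14086 for thapsigargin, 894 to 8496 for AA_Dep, and for shATF4 from 0 to 2160 in DMSO, 38 to 4044 in TGFbeta, 0 to 13731 in thapsigargin and 0 to 1849 in AA_Dep. Interactions in LX-2 ran from 0 to 184 for TGFbeta, 0 to 12126 for thapsigargin and 1 to 1971 for AA_Dep. The highest values came without shCtrl thapsigargin replicate 1 in the thapsigargin comparisons and without replicate 2 of that group in the others. Where edgeR called 0 genes, between 250 and 3549 had an unadjusted p under 0.05. In HMLE the ranges were 8982 to 9609 for Twist_OE, 5324 to 5888 for thapsigargin and 9686 to 9979 for AA_Dep; for shATF4, 1101 to 1470 in DMSO, 7143 to 7592 in Twist_OE, 2963 to 3792 in thapsigargin and 2063 to 2255 in AA_Dep; and for the interactions 4530 to 5050, 499 to 1061 and 577 to 722. Between lines they were 2451 to 12171 for thapsigargin and 2024 to 8176 for AA_Dep, and for shATF4 26 to 1276 in DMSO, 56 to 11856 in thapsigargin and 32 to 1456 in AA_Dep.

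Without LX-2 shCtrl thapsigargin replicate 2, overlaps were 943 genes (TGFbeta against shATF4 in TGFbeta, opposite), 1245 (TGFbeta and thapsigargin), 1280 (TGFbeta and AA_Dep), 4681 (thapsigargin and AA_Dep, 4125 after window medians were removed, when the AA_Dep count was 7899), 1617 (shATF4 in DMSO and TGFbeta), 2522 and 3790 (thapsigargin and AA_Dep between lines), 502 (shATF4 in AA_Dep between lines), 1314 (TGFbeta and Twist_OE) and 1407 (shATF4 in those). Of the lists, 3 changed direction without that library: epithelial genes in the LX-2 thapsigargin interaction went up (camera 0.011, and up to 0.62 without another library), and in the between-line shATF4 effect in thapsigargin aminoacyl-tRNA synthetases went up (0.00073, and up to 0.94) and mitochondrially encoded genes down (3.2e-05, and up to 0.27). The cause was not tested.

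The DESeq2 Wald test gave 1146 genes for LX-2 TGFbeta, 3542 for AA_Dep, 353, 925, 4197 and 222 for shATF4 in DMSO, TGFbeta, thapsigargin and AA_Dep, and 36, 712 and 200 for the interactions with TGFbeta, thapsigargin and AA_Dep; between lines it gave 363, 4012 and 393 for shATF4 in DMSO, thapsigargin and AA_Dep. With no count filter there were 93, 3969 and 55 for LX-2 shATF4 in DMSO, thapsigargin and AA_Dep, 4, 1639 and 47 for the interactions and 2989 for shATF4 in thapsigargin between lines. DESeq2's size factors gave 2210 for the last. The cause was not tested.

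Fitting only the compared groups gave LX-2 5209 for TGFbeta, 0 for thapsigargin (1750 unadjusted), 5569 for AA_Dep, 2896, 6952, 0 (215 unadjusted) and 84 for shATF4 in DMSO, TGFbeta, thapsigargin and AA_Dep, and 583, 0 (768 unadjusted) and 666 for the interactions. It gave 1378 for the HMLE AA_Dep interaction, and between lines 35 and 6165 for thapsigargin and AA_Dep and 1625, 0 (718 unadjusted) and 139 for shATF4 in DMSO, thapsigargin and AA_Dep. In this fit the discordant library enters only where its group is compared, so its effect is confined to the thapsigargin comparisons.

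A minimum absolute log2 change of 1 left 3949 genes for HMLE Twist_OE, 1157 for thapsigargin, 3865 for AA_Dep, 222, 2760, 518 and 527 for shATF4 in DMSO, Twist_OE, thapsigargin and AA_Dep, and 1963, 80 and 155 for the interactions. Overlaps were then 2297 (Twist_OE against shATF4, opposite), 477 (HMLE thapsigargin and AA_Dep), 246 and 330 (thapsigargin and AA_Dep between lines) and 43 (shATF4 in TGFbeta and Twist_OE).

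With the replicate block, counts were 14, 24 and 10 for LX-2 shATF4 in DMSO, thapsigargin and AA_Dep, 14 and 3 for the thapsigargin and AA_Dep interactions, and 339 for shATF4 in thapsigargin between lines. The correlation between groups of the deviations of replicate 1 from replicate 2 had a median of -0.01 in LX-2 and 0.02 in HMLE.

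List results past the threshold with camera's preset correlation, with all libraries or without the discordant library, numbered 139 in LX-2, 114 in HMLE and 73 between lines. With all libraries, 57, 59 and 23 of these lost it with an estimated correlation. At least 33 of those in LX-2 and 17 between lines had passed only without the discordant library and so had no call to lose. In LX-2, those for stress response targets in thapsigargin, AA_Dep and shATF4 in either, and for collagens in TGFbeta, both stresses and shATF4 in DMSO, kept theirs; collagens with shATF4 in TGFbeta did not (0.073, and 0.017 without the discordant library). In HMLE, stress response targets kept it in both stresses and with shATF4 in DMSO and both stresses, and epithelial, mesenchymal and collagen genes in Twist_OE and with shATF4 in it.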

Other observations

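Some changes belong to several comparisons at once, and these genes and lists were picked after their values were seen. With shATF4 in LX-2 the nerve growth factor receptor NGFR was higher in all 4 conditions, by log2 changes of 2.31 in DMSO, 1.90 in TGFbeta, 1.83 in thapsigargin and 1.39 in AA_Dep (adjusted p at most 0.034). In HMLE, CHAC1 was lower with shATF4, with log2 changes of -3.70, -1.98, -3.79 and -4.50 in DMSO, Twist_OE, thapsigargin and AA_Dep. Interferon response genes were higher with shATF4 in AA_Dep in both lines, at medians of 1.73 in LX-2 and 1.47 in HMLE, though with 16 LX-2 libraries 0 of 21 passed over all genes and HMLE shATF4 AA_Dep had 1 library. The LX-2 shATF4 AA_Dep libraries lay far apart for some of these genes, with OAS1 at 29.8 ± 20.4 CPM and IFI44L at 12 ± 9.6. With shCtrl these stood at 3.32 ± 2.17 and 0.947 ± 0.689.

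The counts of genes on or off by condition were chosen only after the data were seen. Genes with at least 1 CPM in all libraries of 1 HMLE condition and less than 0.1 CPM in all others numbered 11 in Twist_OE (among them DCN, CDH11, PRRX1 and FOXF1) and 5 in AA_Dep (FUOM, IFNB1, IFNL2, MGMT and SERPINB9), and 0 in DMSO and in thapsigargin. In LX-2, with 15 libraries, 6 genes were on in thapsigargin and AA_Dep alone (CLEC4OP, KAZN-AS1, KCNJ2, LNCAROD, PCDH11X and SSX1) and 4 were off there alone (CEROX1, KCNMB1, SOX8 and VWA1), while the other 2 splits of the 3 treatments gave 0.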
